A study of Homo sapiens with 16 samples.

How the data were processed

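Gene expression was measured in HEK293 cells, a human embryonic kidney line, that had been transfected for 24 h with a plasmid for the mineralocorticoid receptor (MR; gene NR3C2) at 500 ng per well. The cells were then treated for 4 h with vehicle, with 100 nM deoxycorticosterone acetate (DOC, a mineralocorticoid receptor agonist), with 10 nM phorbol 12-myristate 13-acetate (PMA, a phorbol ester that activates protein kinase C), or with both. Each of the 4 groups held 4 arrays, which the labels number as biological replicates, so p-values measure the spread between biological replicates as labelled. The labels do not say what a replicate number has in common across groups. The numbers were taken to pair the arrays of PMA with those of DOC plus PMA, from the data alone, because deviations from the group means correlated above 0.1 in all 4 same-number pairs (0.157 to 0.549). They were not taken to pair any other 2 groups, where at most 3 of 4 pairs did. The pairing is uncertain, and the main fit did not use it. The block of replicate numbers tried as another setting covered all 16 arrays, so it does not test this pairing alone. PMA replicates 1, 2 and 3 correlated best with their own number among the DOC plus PMA arrays. PMA replicate 4 correlated more with DOC plus PMA replicate 3 (0.335) than with its own number (0.157). PMA replicate 2 correlated as closely with DOC replicate 1 (0.554).

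Biotin-labelled cRNA was made from 100 ng of total RNA with a 3' IVT kit and hybridised to the Affymetrix PrimeView array, per the labels' protocols. The deposited values were log2 RMA signals, made in Affymetrix Expression Console per the submitters' processing notes, whose versions are not given in the sources used here. RMA (robust multi-array average) corrects background, forces all arrays to a common distribution and summarises the probes of each probe set. Because of the common distribution, a change of all transcripts in one direction cannot be seen in these values. The table held 1 column per array and 49293 probe sets, with values from 1.21 to 13.8 and array medians from 4.91 to 4.96. It held 0 columns that did not belong to these 16 arrays. Control probe sets were not used here, so no check of 5' against 3' signal was made.

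Probe sets were named from the platform annotation table. It paired 44988 probe sets with 1 gene and 1832 with several, and 2473 had no name in it. Of the single-gene probe sets, 44961 matched a current gene by gene identifier, and together they covered 18132 distinct genes. A probe set was kept if it lay at or above the 40th percentile of its array in at least 4 of the 16 arrays, which left 30613 probe sets, 28226 of them with 1 gene. Each gene was then represented by its kept probe set with the highest mean over all arrays, which gave 12495 genes. Of these, 7495 had several kept probe sets, and among the genes named in the text those of CORO1A, NEDD4L and SMAD6 differed in sign for PMA against vehicle. No genome build is named in the sources used here, so no coordinates are given.

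Group means were fitted to the 16 arrays with lmFit in limma 3.58.1 under R 4.3.3, with moderated variances from eBayes. The contrasts were PMA, DOC and DOC plus PMA each against vehicle, DOC plus PMA against PMA and against DOC, the interaction (the DOC effect with PMA minus the DOC effect without), and the main effects of DOC and of PMA (each the mean of its effect at both levels of the other agent). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the contrast, two-sided, with no fold minimum. Fold changes are log2 differences, given as ± standard error (SE) from this fit. Levels are given as mean ± SD of 4 arrays. There are no read depths for arrays, and the number of arrays limits the precision. The median SE was 0.0879 for a difference of 2 groups, 0.124 for the interaction and 0.0621 for a main effect.

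The fit was tested on simulated values for the same 12495 genes, with known changes added to 200 of them in both DOC groups and to another 200 in DOC plus PMA alone. The second 200 carry the interaction and a smaller DOC main effect, so calls among them are true there too. For DOC against vehicle it recovered 31.3% of genes changed by 0.3 on the log2 scale, 80.6% of those changed by 0.5 and 98.5% of those changed by 1. For the DOC main effect these shares were 82.1%, 97.0% and 100%. Both refer to the first 200. For the interaction they were 5.97%, 52.2% and 100% of the second 200. Of the simulated calls, 3 of 143, 18 of 320 and 5 of 110, in this order, were false. The simulated values had independent noise and more calls than the data, where 15, 54 and 11 genes passed in this order. With fewer changed genes the adjustment is stricter, so the shares recovered in the data may be lower.

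In all, 17 gene lists and 3 marker lists of other cell types were fixed. They covered the AP-1 family, AP-1 inflammatory and matrix targets, immediate early genes, ERK pathway feedback, NF-kB feedback and targets, corticosteroid-induced genes, aldosterone-regulated sodium transport, steroid receptors and chaperones, phorbol ester receptors and metallothioneins. Further lists held the circadian clock, cholesterol synthesis, the unfolded protein response, mitotic and cell cycle genes, interferon-induced genes, p53 targets, SRF and MRTF cytoskeletal targets, and leukocyte, endothelial and fibroblast markers. Some genes stand in several lists. The 20 lists were tested in 6 contrasts with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists of a contrast. Camera compares a list with all other genes. Each test was repeated with the correlation estimated from the data and with fry, which does not compare a list with other genes.

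Named genes follow a rule. For PMA against vehicle, DOC against vehicle and DOC plus PMA against PMA they are the 10 largest rises and 10 largest falls among genes that passed, or fewer where fewer passed. For DOC plus PMA against vehicle, DOC plus PMA against DOC and the interaction they are the 5 and 5 by the same rule. For each list in the first 3 of these comparisons, up to 4 members that passed with the smallest p are named, or the 1 with the smallest p where none passed. NR3C2, NR3C1 (the glucocorticoid receptor) and all tested AP-1 family members are always included, and genes with only a locus or clone name were passed over. A gene named outside this rule is said to have been chosen after its values were seen. The groups, contrasts, test, filter, lists, naming rule and other settings to try were set before the data were examined.

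The other settings tried were no filter on dim probe sets, a filter at the 60th percentile, every probe set tested, the mean over the kept probe sets of a gene, cyclic loess, a common array median, a trended and robust variance, array weights, the replicate number as a block, a minimum of 1.5-fold, only the 2 groups compared, and leaving out each of the 16 arrays in turn. For the correlations of effects, a restriction to genes past the threshold was also planned. One alternative, without 3 arrays that deviated together, was chosen after seeing the data. Chance agreement between contrasts that share the vehicle arrays was simulated 100 times. All 16 arrays were used. Transcripts measured by near-identical sequences, such as TUBA3D and TUBA3E, the metallothioneins, and HSPA6 with its relative HSPA7, are uncertain at the level of the single gene.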

Results

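The data were 16 arrays of HEK293 cells transfected with the mineralocorticoid receptor plasmid, 4 for each of vehicle, DOC, PMA and DOC plus PMA, all collected after 4 h of treatment. The title of the series places the question in how this receptor acts on AP-1 transcription factors and inflammatory signalling. No group without the receptor plasmid was analysed here, so a response to DOC cannot be assigned to this receptor rather than to other steroid receptors of the cells. Across 12495 genes, arrays of one group correlated at 0.992 to 0.997, and their root mean square difference was 0.185 to 0.311 on the log2 scale. The first principal component held 74.6% of the total variance. PMA replicate 2, DOC replicate 1 and DOC plus PMA replicate 2 deviated from their groups in the same genes, with pairwise correlations of their deviations of 0.425 to 0.554. Without these 3 arrays, an alternative chosen after seeing the data, 6271 genes passed for PMA against vehicle, 11 for DOC against vehicle, 46 for DOC plus PMA against PMA and 9 for the interaction. All p-values for genes are from limma, adjusted by the Benjamini-Hochberg method.

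PMA against vehicle asks what phorbol ester signalling did in the absence of added steroid. The 10 largest named rises were between 4.89 and 6.45 on the log2 scale. EGR3, a zinc finger transcription factor of the immediate early class, rose by 6.45 ± 0.12 (adjusted p = 4.47e-17, n = 4 per group, limma). CXCL8, the neutrophil chemokine interleukin-8, rose by 6.45 ± 0.16, and the monocyte chemokine CCL7 by 5.46 ± 0.14. ARC, an activity-regulated cytoskeletal protein, rose by 6.11 ± 0.21, the small GTPase ARL14 by 5.99 ± 0.11, the matrix metalloproteinase MMP10 by 5.75 ± 0.14 and the transcription factor EGR1 by 5.63 ± 0.13. FOS rose by 5.65 ± 0.11, C11orf96 by 5.27 ± 0.13 and the protease inhibitor TFPI2 by 4.89 ± 0.10. EGR3, ARL14, MMP10 and CCL7 had vehicle signals of 2.93, 3.21, 2.54 and 2.56, far below the array medians of 4.91 to 4.96, where log2 changes can be understated, so the order of these rises is uncertain. The largest falls were smaller. All but those of TXNIP, SMAD6 and POU3F2 ended below the array medians with PMA, from 2.98 for LIPT2-AS1 to 4.68 for SKIDA1. There a fall can be understated too. SKIDA1 fell by 2.47 ± 0.12 (adjusted p = 1.82e-11), TXNIP, a thioredoxin-binding protein that limits glucose uptake, by 2.26 ± 0.15, and SMAD6, an inhibitor of BMP signalling, by 2.05 ± 0.10. Zinc finger genes were among them, with ZNF449 at −2.24 ± 0.13, ZFP14 at −1.85 ± 0.11 and ZNF33B at −1.82 ± 0.10. THNSL1 was at −1.96 ± 0.10, ENPP5 at −1.85 ± 0.11, LIPT2-AS1 at −1.85 ± 0.17 and the neural transcription factor POU3F2 at −1.77 ± 0.10.

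Of the 13 tested AP-1 family genes, 8 rose with PMA, 1 fell and 4 did not pass (9 and 1 adjusted over the list alone). After FOS, the largest rises were FOSB at 4.38 ± 0.20, FOSL1 at 2.60 ± 0.13, JUNB at 2.55 ± 0.15 and FOSL2 at 1.55 ± 0.11. ATF3 rose by 1.05 ± 0.10, JUN by 0.92 ± 0.07 and JUND by 0.30 ± 0.10. BATF3 fell by 0.28 ± 0.08 (adjusted p = 0.00941). ATF2 at 0.20 ± 0.09, ATF7 at 0.17, BATF2 at −0.27 and JDP2 at 0.06 did not pass. JUND did not pass without vehicle replicate 4 (0.22, adjusted p = 0.0970) or PMA replicate 1 (0.26, adjusted p = 0.0739), and BATF3 not after cyclic loess (−0.20) or a common median (−0.19). ATF2 passed with averaged probe sets (0.35, adjusted p = 7.72e-05), after cyclic loess (0.0313), with a common median (0.00475) or without vehicle replicate 4 (0.0216), and ATF7 after cyclic loess (0.0229), with a common median (0.0178) or without PMA replicate 1 (0.0356). The family shifted upward against all other genes, with a median of 0.92 (camera adjusted p = 6.98e-07, and adjusted p = 0.00452 with an estimated correlation).

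**Figure D1:**
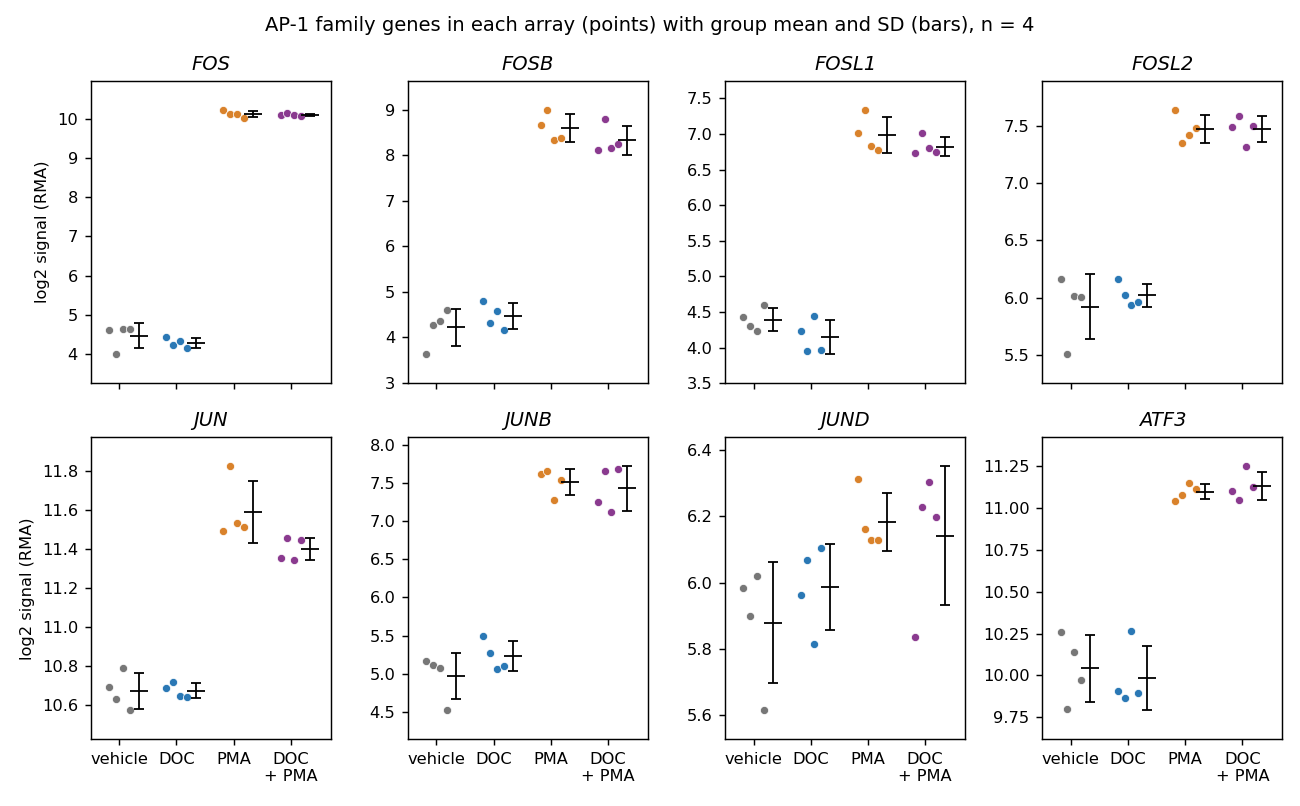
Log2 RMA signal of 8 AP-1 family genes in vehicle, DOC, PMA and DOC plus PMA, with a point per array and bars for the group mean and SD (n = 4). FOS was at 4.47 ± 0.31 in vehicle and 4.28 ± 0.12 in DOC, against 10.12 ± 0.08 in PMA and 10.10 ± 0.03 in DOC plus PMA.

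Inflammatory and matrix targets of AP-1 rose almost as a whole with PMA, 17 of 18 members over all genes and also adjusted over the list alone, with a median of 1.89 (camera adjusted p = 2.29e-17). Among them were PTGS2, the inducible cyclooxygenase, at 4.10 ± 0.11 and the chemokine CCL20 at 3.73 ± 0.20, while IL1B at 0.15, named after its value was seen, did not pass. Of 29 immediate early genes 25 rose, including TRIB1 at 3.96 ± 0.08 and IER2 at 2.28 ± 0.07 (camera adjusted p = 1.09e-18). The 3 that fell, named after their values were seen, were the helix-loop-helix inhibitors ID1 at −0.51, ID2 at −0.81 and ID3 at −1.76, and the counts were the same adjusted over the list alone. The ERK feedback list had 15 rises, such as PHLDA1 at 3.83 ± 0.09, the receptor EPHA2 at 3.22 ± 0.11, the phosphatase DUSP6 at 3.61 ± 0.13 and the inhibitor SPRY2 at 2.19 ± 0.07, and 2 falls among 17 members (15 and 2 adjusted over the list alone, camera adjusted p = 3.77e-14). With an estimated correlation these 3 lists had adjusted p = 0.00408, 0.00408 and 0.0270.

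A further 3 lists shifted upward at the preset correlation and not with an estimated one. NF-kB feedback and targets had 9 rises and 2 falls among 17 members (9 and 2 adjusted over the list alone), among them the subunits NFKB1 at 1.43 ± 0.09 and RELB at 1.64 ± 0.14, NFKBIZ at 1.26 ± 0.11 and CD83 at 1.63 ± 0.13 (camera adjusted p = 0.000811, and adjusted p = 0.184 with an estimated correlation). Corticosteroid-induced genes had 15 rises and 4 falls among 25 (15 and 4 adjusted over the list alone), with DUSP1 at 2.19 ± 0.07, ZFP36 at 3.82 ± 0.14, GADD45B at 3.60 ± 0.08 and the sodium-transport kinase SGK1 at 1.43 ± 0.08, and with TSC22D3, the glucocorticoid-induced leucine zipper, at −1.18 (camera adjusted p = 1.19e-05, and adjusted p = 0.132 with an estimated correlation). SRF and MRTF targets had 10 rises and 1 fall among 18 (10 and 1 adjusted over the list alone), with the matricellular proteins CCN1 at 2.82 ± 0.09 and CCN2 at 3.72 ± 0.20, FHL2 at 1.36 ± 0.06 and VCL at 0.78 ± 0.07 (camera adjusted p = 3.86e-06, and adjusted p = 0.107 with an estimated correlation).

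The 13 other lists were not called with PMA. Aldosterone-regulated sodium transport had 5 rises and 1 fall among 11 (5 and 1 adjusted over the list alone, adjusted p = 0.0555), including the ubiquitin ligase NEDD4L at 1.10 ± 0.08, EDN1 at 1.29 ± 0.14 and ATP1B1 at 0.31 ± 0.07. Its test passed without vehicle replicate 1 (0.0376), vehicle replicate 2 (0.0463), PMA replicate 2 (0.0405) or DOC replicate 2 (0.0494). It passed too with averaged probe sets (0.0326), with array weights (0.0444) or without the 3 arrays that deviated together (0.0462). Phorbol ester receptors had 9 falls and 2 rises among 15 (10 and 2 adjusted over the list alone, median −0.30, adjusted p = 0.150), with PRKCQ at −0.79 ± 0.09, PRKCZ at −0.45 ± 0.06, PRKCD at 1.01 ± 0.06 and PRKCI at 0.57 ± 0.12. Cholesterol synthesis had 10 falls and 2 rises among 16 (11 and 2 adjusted over the list alone, median −0.30, adjusted p = 0.0822), with SQLE at −1.08 ± 0.08 and PMVK at −0.64 ± 0.08 against HMGCS1 at 0.78 ± 0.10 and INSIG1 at 0.75 ± 0.08. Mitotic and cell cycle genes had 13 falls and 3 rises among 27 (14 and 3 adjusted over the list alone, median −0.20, adjusted p = 0.112), with KIF20A at −0.76 ± 0.07, KIF11 at −0.52 ± 0.07, MCM2 at −0.45 ± 0.07 and TTK at −0.45 ± 0.07. With no filter on dim probe sets, cholesterol synthesis (adjusted p = 0.0204) and the mitotic list (0.0262) passed. Steroid receptors and chaperones had 3 rises and 2 falls among 12 (2 and 2 adjusted over the list alone, adjusted p = 0.362), with STUB1 at −0.65 ± 0.09, HSPA8 at 0.43 ± 0.07, the co-chaperone FKBP5 at 0.35 ± 0.08 and the coactivator NCOA1 at −0.26 ± 0.08. NCOA1 lay below every vehicle array in 3 of 4 PMA arrays, and did not pass without vehicle replicate 3 (adjusted p = 0.0726) or PMA replicate 1 (0.0521) or under either other scaling.

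Genes of p53 signalling went both ways with PMA, with 8 rises and 8 falls among 18 (8 and 9 adjusted over the list alone, adjusted p = 0.785). The cell cycle inhibitor CDKN1A rose by 1.61 ± 0.15 and GADD45A by 0.93 ± 0.10, while SESN1 fell by 0.96 ± 0.08 and BAX by 0.62 ± 0.06. Clock genes had 3 rises and 4 falls among 13 (3 and 4 adjusted over the list alone, adjusted p = 0.785), with BHLHE40 at 1.64 ± 0.12, PER2 at 1.11 ± 0.12, CRY1 at 1.00 ± 0.11 and NR1D2 at −0.81 ± 0.09. The unfolded protein response had 7 rises and 4 falls among 20 (7 and 4 adjusted over the list alone, adjusted p = 0.0656, and 0.0492 without PMA replicate 2), with PPP1R15A at 1.02 ± 0.13, ATF4 at 0.36 ± 0.06, EDEM1 at 0.47 ± 0.08 and SDF2L1 at −0.56 ± 0.09. This list test also passed with array weights (0.0431) or without the 3 arrays that deviated together (0.0337). In the metallothioneins 2 of 7 fell, MT1X by 0.46 ± 0.07 and MT1F by 0.46 ± 0.10 (2 adjusted over the list alone, adjusted p = 0.928). Interferon-induced genes had 4 falls among 24 (4 adjusted over the list alone, median −0.28, adjusted p = 0.362), IRF9 at −0.85 ± 0.10, IFIT1 at −1.32 ± 0.22, IFIT3 at −0.79 ± 0.24 and OAS2 at −1.15 ± 0.37. IFIT3 and OAS2 lay below every vehicle array in 3 of 4 PMA arrays. Without vehicle replicate 1 neither passed (−0.53 and −0.77), OAS2 did not pass without PMA replicate 2 (−0.93), and the list test passed without PMA replicate 1 (median −0.46, adjusted p = 0.0259). The sign of the test differed from that of the median in 3 of these lists, the metallothioneins (median 0.05, mean −0.07, test downward), the clock (median −0.17, mean 0.08, test upward) and p53 targets (median −0.15, mean 0.01, test upward).

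Markers of other cell types showed small differences with PMA. Of the 12 tested markers, 11 were counted as below every array median, near the floor, so these differences do not show that the cells expressed them. Among the 11, CORO1A and TIE1 had means of 5.01 and 4.99 with PMA, just above the highest array median of 4.96. Leukocyte markers had 2 rises among 4 (2 adjusted over the list alone, adjusted p = 0.375), CORO1A at 0.40 ± 0.12 and CD68 at 0.43 ± 0.16. Endothelial markers had 3 rises and 1 fall among 5 (3 and 1 adjusted over the list alone, adjusted p = 0.231), TIE1 at 0.47 ± 0.09, PECAM1 at 0.30 ± 0.08, ESAM at 0.23 ± 0.09 and EGFL7 at −0.19 ± 0.07. None of 3 fibroblast markers passed over all genes (2 rises and 1 fall adjusted over the list alone, adjusted p = 0.595), the nearest being POSTN at −0.32 (adjusted p = 0.0541), which passed in 3 other settings besides the block of replicate numbers (0.0129 to 0.0273). CD68 lay above every vehicle array in 2 of 4 PMA arrays, ESAM in 1 of 4 and PECAM1 in 3 of 4. CD68 did not pass without vehicle replicate 2, 3 or 4 or PMA replicate 1 or 2 (adjusted p = 0.0720 to 0.107), ESAM not without vehicle replicate 1, 2 or 4 or PMA replicate 1, 3 or 4 (0.0521 to 0.134), and EGFL7 not without vehicle replicate 1 or PMA replicate 3 (0.0869 to 0.0971). CORO1A did not pass when the probe sets of a gene were averaged (adjusted p = 0.233).

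In all, 5869 of 12495 genes passed for PMA against vehicle, 2206 higher and 3663 lower, and 6641 had an unadjusted p under 0.05 where 625 would by chance. At least 2-fold differences were seen in 255 genes upward and 202 downward, and at least 4-fold in 76 and 4. Of 91 named genes that passed, 85 had all 4 PMA arrays beyond all 4 vehicle arrays. Chance gives this for 2.86% of unselected genes, but these were selected on the same arrays, so their separation is no further evidence. The balance of directions depended on scaling, with 37.6% of the called genes higher in the deposited values, 46.5% after cyclic loess (2689 higher, 3092 lower) and 55.4% with a common median (3418 higher, 2748 lower).

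DOC against vehicle asks what the mineralocorticoid did alone. Of the 15 genes that passed, 5 belonged to the list of corticosteroid-induced genes, namely PDK4, SGK1, RGS2, TSC22D3 and FKBP5. PDK4, a kinase that restrains pyruvate dehydrogenase, rose by 1.92 ± 0.15, or 3.77-fold (adjusted p = 1.67e-06, n = 4 per group, limma). The sphingosine-1-phosphate receptor S1PR3 rose by 1.06 ± 0.08, the phosphatase and actin regulator PHACTR3 by 1.05 ± 0.10 and SGK1 by 0.93 ± 0.08 (adjusted p = 5.61e-06). TUBA3E, an alpha tubulin with a near-identical relative, rose by 0.85 ± 0.09, the ADP-ribosyltransferase TIPARP by 0.81 ± 0.11, RGS2, a regulator of G protein signalling, by 0.64 ± 0.08, and PHLDA1 by 0.63 ± 0.09. TSC22D3 rose by 0.63 ± 0.09 and FKBP5 by 0.58 ± 0.08 (adjusted p = 0.00121). NFKBIA, an inhibitor of NF-kB, rose by 0.71 ± 0.12 (adjusted p = 0.0139), but not past the threshold without vehicle replicate 3, vehicle replicate 4, DOC replicate 1 or DOC replicate 4 (adjusted p = 0.0629 to 0.0879), and TSC22D3 did not pass with averaged probe sets (0.65, adjusted p = 0.0610). The other 4 genes past the threshold were 0.47 to 0.62 higher. All 11 named genes had every DOC array above every vehicle array, but they were selected on these arrays, so this is no further evidence.

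In total 15 genes passed in limma for DOC against vehicle, all of them higher. No gene was lower at the threshold, and 386 genes had an unadjusted p under 0.05 in either direction, below the 625 of chance. Of 25 corticosteroid-induced genes 5 rose (12 adjusted over the list alone), and the list shifted upward with a median of 0.28 (camera adjusted p = 1.27e-30, and adjusted p = 0.00156 with an estimated correlation). None of the 13 AP-1 family genes passed, their changes ran from −0.24 for FOSL1 to 0.26 for JUNB, and the list was not called (adjusted p = 0.655). The AP-1 target list had no member past the threshold (1 rise adjusted over the list alone, median 0.04, adjusted p = 0.988), its smallest p being that of PLAUR at 0.42. Metallothioneins had a median of 0.15 with 0 of 7 past the threshold (1 adjusted over the list alone, camera adjusted p = 0.0124, and adjusted p = 0.524 with an estimated correlation). Endothelial markers had a median of 0.17 with 0 of 5 past it (1 adjusted over the list alone, camera adjusted p = 0.0124, and adjusted p = 0.226 with an estimated correlation), led by PECAM1 at 0.32. Of these 5 markers, 4 lay below every array median, PECAM1 among them at 3.98 in vehicle. The metallothionein call was lost without vehicle replicate 3 (0.0814), vehicle replicate 4 (0.0646), DOC replicate 1 (0.155) or DOC replicate 2 (0.103), and the endothelial call without vehicle replicate 4 (0.207) or DOC replicate 2 (0.0650). At the 60th percentile filter (0.255) or without the 3 arrays that deviated together (0.157) the metallothionein call was also lost. Interferon-induced genes were not called (median 0.13, adjusted p = 0.382) but passed without vehicle replicate 1 (0.39, adjusted p = 6.32e-12) or DOC replicate 2 (0.21, adjusted p = 0.0329), and the NF-kB list, not called at adjusted p = 0.210, passed without DOC replicate 2 (0.0329).

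DOC plus PMA against PMA asks what the steroid did while phorbol ester signalling was active. PDK4 rose by 3.09 ± 0.15, or 8.52-fold (adjusted p = 6.08e-10, n = 4 per group, limma), and CYP26A1, which breaks down retinoic acid, by 2.74 ± 0.13, or 6.67-fold (adjusted p = 6.08e-10). APOLD1, an apolipoprotein L domain protein of vascular cells, rose by 2.16 ± 0.13, TIPARP by 2.00 ± 0.11, the actin-binding protein XIRP1 by 1.64 ± 0.19, RGS2 by 1.33 ± 0.08 and TXNIP by 1.15 ± 0.15. S1PR3 rose by 1.13 ± 0.08, TSC22D3 by 1.10 ± 0.09, the small GTPase RHOB by 1.08 ± 0.09, SGK1 by 0.96 ± 0.08 and FKBP5 by 0.51 ± 0.08 (adjusted p = 0.00211). The metal-binding proteins MT1X and MT2A rose by 0.55 ± 0.07 and 0.73 ± 0.15. HSPA6, a stress-inducible HSP70 chaperone measured here by a single kept probe set, fell by 2.51 ± 0.21 (adjusted p = 9.33e-07), the ubiquitin ligase RNF122 by 0.57 ± 0.10 (adjusted p = 0.00596) and NRARP, a feedback inhibitor of Notch signalling, by 0.36 ± 0.08 (adjusted p = 0.0448). All 17 named genes that passed had every array of one group beyond every array of the other. They were selected on the same arrays, so their separation adds no evidence.

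In this comparison 48 genes passed, 45 higher and 3 lower, and 544 had an unadjusted p under 0.05, below the 625 of chance. The fit behind these counts did not pair the arrays. With the replicate number as a block over all 4 groups, 56 genes passed. Of 25 corticosteroid-induced genes 7 rose (13 adjusted over the list alone, median 0.29, camera adjusted p = 6.33e-31, and adjusted p = 0.00149 with an estimated correlation). Metallothioneins had 2 rises among 7 (3 adjusted over the list alone, median 0.11, camera adjusted p = 5.98e-07, and adjusted p = 0.0654 with an estimated correlation). AP-1 targets had a median of −0.20 with none of 18 past the threshold (1 lower adjusted over the list alone, camera adjusted p = 0.000344, and adjusted p = 0.3004 with an estimated correlation), and without PMA replicate 1 the call was lost (−0.13, adjusted p = 0.331). The nearest member was PTGS2 at −0.45 ± 0.11 (adjusted p = 0.101), which passed with the replicate number as a block (adjusted p = 0.00922), with averaged probe sets (0.0347), with a common median (0.0462) or without vehicle replicate 1 (0.0329). No AP-1 family gene passed and the list was not called (median −0.02, adjusted p = 0.167), with JUN at −0.19. The count was 31 without DOC plus PMA replicate 4. MT2A did not pass without vehicle replicate 3, PMA replicate 2, 3 or 4, or DOC plus PMA replicate 1, 2 or 4 (adjusted p = 0.0512 to 0.156), and NRARP passed only in the absence of vehicle replicate 4, DOC replicate 1, DOC replicate 4 or DOC plus PMA replicate 2, with 0.0576 to 0.186 when any other array was left out.

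Among lists not called in this comparison, ERK feedback (median −0.12, adjusted p = 0.06004) passed without PMA replicate 3 (0.0149), DOC replicate 1 (0.0478) or DOC plus PMA replicate 2 (0.00210), and with the replicate number as a block (0.0417). ERK feedback also passed with averaged probe sets (0.0461) and without the 3 arrays that deviated together (0.00579). Phorbol ester receptors (median 0.04, adjusted p = 0.0538) passed without vehicle replicate 1, PMA replicate 1 or 2, DOC replicate 1 or 4, or DOC plus PMA replicate 1 or 4 (0.0340 to 0.0481), and with the block (0.0433). That list also passed with no filter (0.0318), cyclic loess (0.0495), a common median (0.0428) or array weights (0.0471). Interferon-induced genes (median 0.07, adjusted p = 0.860) passed without PMA replicate 1 (0.28, adjusted p = 3.71e-06).

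**Figure D2:**
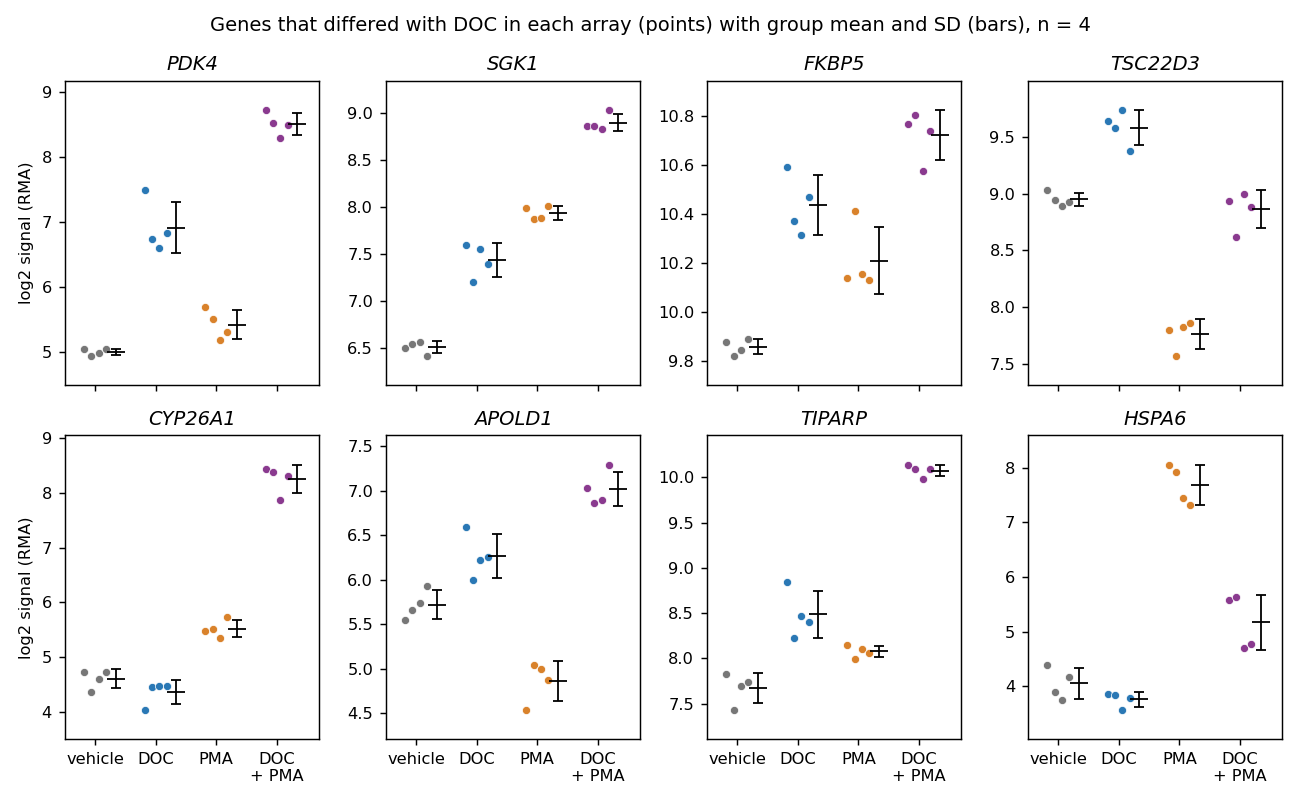
Log2 RMA signal of 8 genes in vehicle, DOC, PMA and DOC plus PMA, with a point per array and bars for the group mean and SD (n = 4). CYP26A1 was at 4.61 ± 0.17 in vehicle, 4.36 ± 0.22 in DOC, 5.52 ± 0.16 in PMA and 8.25 ± 0.26 in DOC plus PMA, and HSPA6 at 4.05 ± 0.28, 3.76 ± 0.14, 7.69 ± 0.36 and 5.17 ± 0.51.

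The interaction tests whether the DOC response differed between cells with and without PMA, and 11 genes passed, 9 with a more positive and 2 with a more negative DOC effect under PMA. CYP26A1 differed most, by 2.98 ± 0.18 (adjusted p = 5.65e-08), followed by APOLD1 at 1.61 ± 0.19 (adjusted p = 0.000531), XIRP1 at 1.59 ± 0.27, TXNIP at 1.24 ± 0.21 and TIPARP at 1.18 ± 0.15 (adjusted p = 0.00137). On the negative side were HSPA6 at −2.23 ± 0.30 (adjusted p = 0.00200) and PHLDA1 at −0.77 ± 0.13. The remaining 4, named after their values were seen, were PDK4 at 1.18 ± 0.21, the heparan sulfate sulfotransferase HS3ST3B1 at 0.76 ± 0.11, RHOB at 0.73 ± 0.13 and RGS2 at 0.69 ± 0.12. PMA alone placed these genes differently, with APOLD1 at −0.86, TXNIP at −2.26 and CYP26A1 at 0.91 in PMA against vehicle. Without PMA, signals lay below the array medians for CYP26A1 (4.61 in vehicle, 4.36 in DOC), XIRP1 (4.02 and 4.07) and HSPA6 (4.05 and 3.76), where a DOC effect can be understated, so the sizes and order of these differences are uncertain. CYP26A1, APOLD1, TIPARP, HSPA6 and HS3ST3B1 passed whichever single array was left out.

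The other 6 did not. XIRP1 was lost without vehicle replicate 1, 2 or 3, PMA replicate 4, DOC replicate 4, or DOC plus PMA replicate 1, 2 or 4 (adjusted p = 0.0518 to 0.0726), and TXNIP without vehicle replicate 2 or 4, PMA replicate 1 or 4, DOC replicate 4, or DOC plus PMA replicate 1 or 2 (0.0511 to 0.0690). PHLDA1 was lost without vehicle replicate 2 or 4, DOC replicate 2 or 4, or DOC plus PMA replicate 4 (0.0536 to 0.0726), and RGS2 without vehicle replicate 3, PMA replicate 1 or 4, DOC replicate 2 or 4, or DOC plus PMA replicate 1 or 4 (0.0548 to 0.0735). PDK4 held without PMA replicate 1, DOC replicate 1 or DOC plus PMA replicate 3 and was lost without any other array (1.07 to 1.21, adjusted p = 0.0628 to 0.131). RHOB held without vehicle replicate 4, PMA replicate 2, DOC replicate 1 or DOC plus PMA replicate 3 and was lost otherwise (0.0538 to 0.0845), and its averaged probe sets gave 0.17. The count of 11 became 6 without vehicle replicate 2, 7 without vehicle replicate 3, 6 without PMA replicate 4, 7 without DOC replicate 2, 5 without DOC replicate 4, 6 without DOC plus PMA replicate 1, 7 without replicate 2 and 6 without replicate 4 of that group.

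No AP-1 family gene passed the interaction test, with values from −0.52 for FOSB to 0.20 for BATF3, and the family was not called (adjusted p = 0.765). AP-1 targets had a median interaction of −0.19 with 0 of 18 past the threshold in limma (camera adjusted p = 0.0405, and adjusted p = 0.759 with an estimated correlation). That call was lost without vehicle replicate 3 (0.0560), vehicle replicate 4 (0.107), PMA replicate 1 (−0.08, adjusted p = 0.646), DOC replicate 3 (0.0827), DOC replicate 4 (0.118) or DOC plus PMA replicate 4 (0.0991), and under both other scalings. The 60th percentile filter removed it too (0.171). Corticosteroid-induced genes had 2 members with a more positive DOC effect under PMA among 25 (4 adjusted over the list alone, adjusted p = 0.0772).

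**Figure D3:**
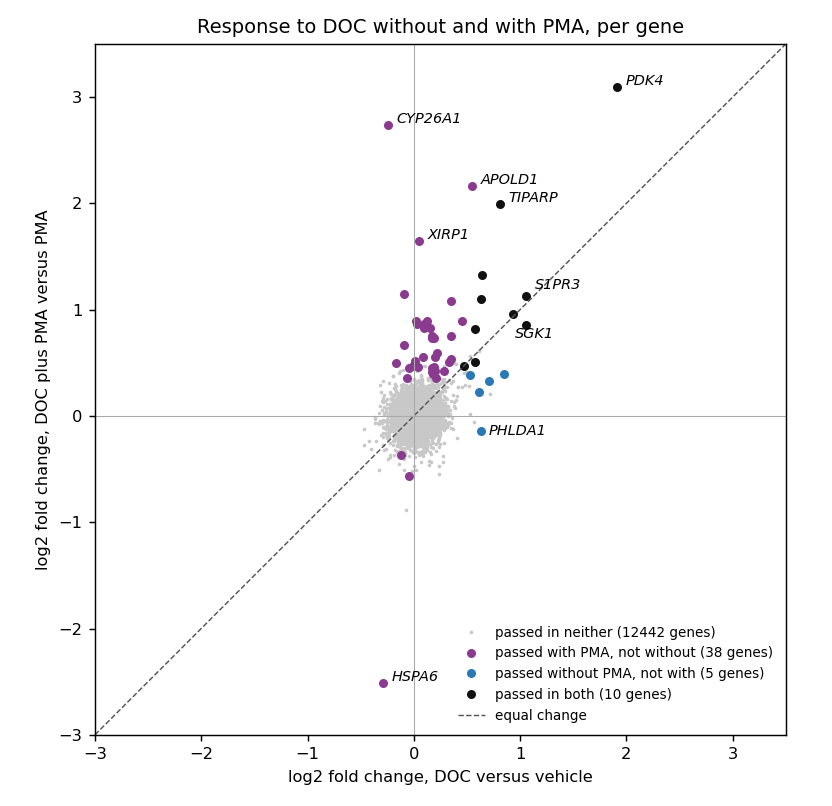
Log2 fold change of DOC plus PMA against PMA (y axis) set against that of DOC against vehicle (x axis), with a point per gene, colours for the comparison in which the gene passed, and a dashed line of equal change. Of the genes raised by DOC, 10 passed in both comparisons, and CYP26A1 at 2.74 and HSPA6 at −2.51 on the y axis lie far from the line.

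Of the 15 genes raised by DOC alone, 10 were also raised by DOC with PMA present, where 0.0540 would be expected of independent lists (Fisher's exact test, two-sided, p = 3.71e-22). Among the 53 genes that passed in either comparison, 42 were higher with DOC in both and 46 had the larger change with PMA. Since 48 of these 53 were included for passing with PMA and 15 for passing without, the selection itself favours a larger change with PMA. Across all 12495 genes the DOC effects without and with PMA correlated at a Pearson r of 0.173 and a Spearman rho of −1.48e-05, and genes are not independent replicates. That r was 0.301 without PMA replicate 2, 0.115 without PMA replicate 3, 0.0934 without PMA replicate 4, 0.0862 without DOC replicate 3. The PMA effects without and with DOC correlated at 0.959 (Spearman rho 0.911).

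DOC plus PMA against vehicle gives the combined response. ARC rose by 6.52 ± 0.21, CXCL8 by 6.18 ± 0.16, EGR3 by 6.15 ± 0.12, FOS by 5.63 ± 0.11 and EGR1 by 5.56 ± 0.13. The largest falls were those of SKIDA1 at −2.38, SMAD6 at −2.19, LIPT2-AS1 at −2.10, ZNF449 at −2.02 and ZFP14 at −1.98. In all 5476 genes passed, 2185 higher and 3291 lower (39.9% higher, against 48.0% after cyclic loess and 55.1% with a common median). AP-1 family genes again had 8 rises and 1 fall among 13 (camera adjusted p = 9.48e-07, and adjusted p = 0.00523 with an estimated correlation). The members were not those of PMA against vehicle, since ATF7 passed here and JUND at 0.26 (adjusted p = 0.0507) did not. JUND passed in 8 other settings (0.00602 to 0.0476), and ATF2 at 0.22 (adjusted p = 0.0583) in 10 (0.000379 to 0.0481). ATF7 at 0.22 and BATF3 at −0.22 were near the threshold. ATF7 was lost without vehicle replicate 1, 2 or 4, PMA replicate 3, DOC replicate 2 or 4, or DOC plus PMA replicate 1 or 4 (adjusted p = 0.0504 to 0.153), and BATF3 without any vehicle array or DOC plus PMA replicate 2 or 3 (0.0614 to 0.156) and under both other scalings. Corticosteroid-induced genes had 17 rises and 1 fall among 25 (18 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 2.54e-12, and adjusted p = 0.0186 with an estimated correlation). AP-1 targets had 17 rises among 18 and immediate early genes 25 rises and 3 falls among 29 (camera adjusted p = 7.26e-17 and 4.06e-20). In all 8 of 20 lists were called, 5 of them with an estimated correlation.

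DOC plus PMA against DOC gives the PMA response in the presence of the steroid. EGR3 rose by 6.22, CXCL8 by 6.08, ARC by 6.03, FOS by 5.81 and ARL14 by 5.80, while SKIDA1 fell by 2.24, LIPT2-AS1 by 2.12, ZFP14 by 2.10, ZNF449 by 2.05 and SMAD6 by 2.02. In all 5323 genes passed, 1958 higher and 3365 lower (36.8% higher, against 43.8% after cyclic loess and 52.1% with a common median). AP-1 family genes had 8 rises among 13 (camera adjusted p = 1.72e-07, and adjusted p = 0.00311 with an estimated correlation), of which ATF7 at 0.25 was lost without DOC replicate 1, DOC replicate 2, or DOC plus PMA replicate 1 or 4 (adjusted p = 0.0542 to 0.0962). JUND at 0.15 and ATF2 at 0.15 did not pass, but JUND passed without DOC plus PMA replicate 1 (0.26, adjusted p = 0.0436), and ATF2 with averaged probe sets (0.29, adjusted p = 0.000546), a common median (0.0219) or array weights (0.0276). Of 20 lists 9 were called, 4 of them with an estimated correlation. Of the genes that PMA raised without DOC, 1680 also passed as higher here, where 346 would be expected of independent lists, and 2966 passed as lower in both, where 986 would be.

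Main effects average each agent over both levels of the other. For DOC 54 genes passed, 51 higher and 3 lower, and for PMA 7146 passed, 2710 higher and 4436 lower (37.9% higher, against 45.7% after cyclic loess and 54.7% with a common median). Of the 51 genes raised by DOC, 22 were also raised by PMA, where 11.1 would be expected of independent lists (Fisher's exact test, two-sided, p = 0.000533), and 18 were lowered by it, where 18.1 would be. A gene raised only by the combination has a positive main effect of both agents, so the excess can be partly built in. Among the 22, CYP26A1 was at −0.24 and XIRP1 at 0.05 for DOC against vehicle. RHOB was at 0.06 for PMA against vehicle, while SGK1 rose with each agent alone (0.93 with DOC and 1.43 with PMA). Across genes the main effects correlated at −0.0705. That value was −0.0275 without vehicle replicate 1, −0.0424 without vehicle replicate 3, −0.0405 without PMA replicate 1, −0.106 without PMA replicate 4 and −0.0352 without DOC plus PMA replicate 3. The genes raised by PMA had a median DOC main effect of 0.0028 (camera p = 0.528 with an estimated correlation), with 22 higher and 2 lower among 2710.

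DOC against vehicle and PMA against vehicle share the vehicle arrays. Their changes correlated at 0.127 across genes, against 0.502 in simulations of unchanged groups, and their covariance was 0.00583 against a simulated 0.00480 (range 0.00449 to 0.00504). Real PMA changes add variance that lowers a correlation, so these correlations cannot be compared. With the vehicle arrays split so that each comparison used 2 of them, the mean correlation over 6 splits was 0.0232 (range −0.0632 to 0.107). The mean covariance was 0.00139 (range −0.00334 to 0.00637). The 6 splits reuse the same vehicle arrays, so this range measures no sampling spread and decides nothing about the observed covariance. Of the 15 genes raised by DOC, 9 were raised by PMA, where 2.65 would be expected of independent lists (Fisher's exact test, two-sided, p = 0.000294), and part of that excess may come from the shared arrays.

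NR3C2, the gene of the transfected mineralocorticoid receptor, was at 7.43 ± 0.13 in vehicle, 7.38 ± 0.04 in DOC, 7.21 ± 0.23 in PMA and 7.02 ± 0.18 in DOC plus PMA. It was lower with DOC plus PMA than with vehicle, by −0.41 ± 0.11 (adjusted p = 0.00413, 3 of 4 arrays below every vehicle array), and lower than with DOC, by −0.36 ± 0.11 (adjusted p = 0.00993). PMA against vehicle gave −0.22 ± 0.11 (adjusted p = 0.0967), DOC against vehicle −0.05 and DOC plus PMA against PMA −0.19, none past the threshold. With PMA it passed without PMA replicate 2 (−0.32, adjusted p = 0.0115), vehicle replicate 1 (0.0456) or the 3 arrays that deviated together (0.00390), and with array weights (0.00968). The probe set may not measure the plasmid transcript, which can lack the 3' end that the array targets, so these values do not show how much receptor was expressed. NR3C1, the glucocorticoid receptor gene, was at 9.01 in vehicle and passed in none of these comparisons, with 0.09 for PMA, −0.11 for DOC and −0.25 for DOC plus PMA against PMA. For DOC plus PMA against vehicle NR3C1 passed as lower with averaged probe sets (−0.19, adjusted p = 0.0155). It did so too without the 3 arrays that deviated together (−0.24, adjusted p = 0.0451).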

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

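The tests of floor compression, of a shift shared by the DOC-raised genes, of HSPA1B or HSPA8 as the whole cause, and of genomic span were chosen after their results were seen, as were leaving out 3 arrays and the levels of the marker genes. The other tests were set before theirs.

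A difference between cells with and without PMA in the response to DOC was found by the interaction test for 11 genes: CYP26A1 (2.98 on the log2 scale), APOLD1 (1.61), XIRP1 (1.59), TXNIP (1.24), TIPARP (1.18), PDK4 (1.18), HS3ST3B1 (0.76), RHOB (0.73), RGS2 (0.69), PHLDA1 (−0.77) and HSPA6 (−2.23).

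The 51 genes with a positive DOC main effect had a median interaction of 0.21 (95% interval 0.08 to 0.37 from 10000 resamples of the genes), with 39 of them positive and a median DOC response of 0.54 with PMA against 0.35 without. Compression of dim signals near the array floor would leave no difference in bright genes, yet the 16 genes above the median vehicle level had a median of 0.38 (0.08 to 0.55). Both intervals resample genes that share the same arrays, so neither measures the spread between biological replicates. The evidence against compression thus rests on that median without a measure of replicate spread. The 3 arrays described in the last pattern did not make the difference. Without them the median interaction of the 51 genes was 0.25, against 0.21 with them. The set stood apart from other genes with camera p = 0.000128 at an estimated correlation. The genes were selected for their mean DOC response on the same arrays, so a larger response under PMA may be biological only as a hypothesis. Whether it goes through the mineralocorticoid receptor was not tested, as no group lacked the plasmid.

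HSPA6 was lower with DOC plus PMA than with PMA by −2.51, and lower in all 4 arrays. Signal from HSPA1B or HSPA8 on its probes that scaled with their own would not make the whole fall. The larger of their falls was −0.47 for HSPA1B. HSPA8 did not change (−0.0039 ± 0.066), which argues against its signal as the whole cause. HSPA1B was far brighter than HSPA6 (12.2 with PMA), but it was already at 11.4 in vehicle. There HSPA6 was at 4.05, near the array floor. The scaling was not tested, so signal from HSPA1B as the whole cause is made less likely, not excluded. A single misreporting probe set stays open, because 0 other kept probe sets measured the gene, and signal from other HSP70 genes as part of the cause stays open with a median of −0.24 over HSPA1B and HSPA8. A lower heat shock state of these cultures also stays open, with a median of −0.028 over 13 other heat shock genes but −0.47 for the inducible HSPA1B and −0.26 for DNAJB1 (camera p = 0.0281 with an estimated correlation, none past the threshold). A specific effect of DOC on HSPA6 is among the open explanations and was not tested apart from these.

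PMA replicate 2, DOC replicate 1 and DOC plus PMA replicate 2 deviated together, with correlations of 0.554, 0.549 and 0.425 between their deviations from group means, on a residual component that held 33.1% of the within-group variance. A bias that follows genomic span is a candidate explanation, since the component's gene loadings rose with the genomic span of the gene at a Spearman rho of 0.276 across genes. Genomic span is not transcript length, which was not measured, so a link to RNA quality or labelling was not tested. Other cells in these cultures stay open. The highest median deviation of a leukocyte, endothelial or fibroblast marker list in these arrays was only 0.077, but 11 of the 12 tested markers were counted as below every array median, near the floor. The labels give no batch or date, so a shared preparation was not tested.

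Arrays far from the other 3 of their group were found in 37 of 508 combinations of a gene and a group, where about 1 in 20, or 25.4, would be by chance, and 11 of the 37 lay in the 3 arrays above. Each value here is the log2 signal minus the mean of the other 3 arrays. Among vehicle arrays these were MT2A in replicate 1 (0.55), FOS (−0.62) and NEDD4L (−0.24) in replicate 2, C11orf96 in replicate 3 (0.56), and JUNB (−0.60) and STUB1 (−0.13) in replicate 4. Among DOC arrays they were ATP1B1 (0.27), CYP26A1 (−0.44), EPHA2 (0.44) and MT2A (0.55) in replicate 1, PRKCB in replicate 2 (0.11), and ARC (1.05), ATF3 (0.38), COL1A1 (−0.48), RNF122 (−0.18) and SMAD6 (−0.084) in replicate 3. PMA arrays had MDM2 (0.12), PLAUR (0.44) and TIE1 (−0.26) in replicate 1, EGR3 (0.38), FKBP5 (0.27), JUN (0.31) and MT1F (0.34) in replicate 2, PRKCZ (−0.17) and ZNF449 (0.51) in replicate 3, and ESAM (0.17), SPRY2 (0.022) and TUBA3E (−0.20) in replicate 4. DOC plus PMA arrays had BAX (0.16), CCL7 (0.34) and ZFP14 (−0.094) in replicate 1, CCN2 (0.30), FHL2 (0.17) and HBEGF (0.29) in replicate 2, ATF2 (−0.22) and GADD45A (0.25) in replicate 3, and EDN1 (−0.41) in replicate 4. The mean correlation with the other arrays of its group was set apart as the lowest in PMA replicate 2 (0.993) and DOC replicate 1 (0.994), and as the highest in vehicle replicate 3 (0.996).

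Probe sets without a single named gene lay outside all comparisons of genes. Of the 2387 that were kept, 924 passed for PMA against vehicle, 1 for DOC against vehicle and 9 for DOC plus PMA against PMA.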

How the results depend on the processing

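One alternative, without 3 arrays that deviated together, was chosen after seeing the data. The cause was not tested for any change given here unless the setting itself tests more or fewer genes. Testing every probe set gave 12536 calls for PMA against vehicle, 11593 and 11213 for DOC plus PMA against vehicle and against DOC, 82 for the DOC main effect and 16074 for the PMA main effect, with correlations of 0.0895 and 0.945 for the DOC and PMA effects and 42 DOC-responsive probe sets among PMA-responsive ones. Array weights gave 89 for DOC plus PMA against PMA, 25 for the interaction, 94 for the DOC main effect and 34 DOC-responsive genes among PMA-responsive ones. Requiring 1.5-fold left 1576, 1471, 27 and 1419 genes for PMA against vehicle, DOC plus PMA against vehicle, against PMA and against DOC, and 16 and 1461 for the DOC and PMA main effects. The correlation of the DOC effects was 0.425 over genes past the threshold, 0.117 with no filter and 0.244 without the 3 arrays, and that of the PMA effects 0.971, 0.937 and, at the 60th percentile filter, 0.969. The main effects correlated at −0.0971 without the 3 arrays. Of 31 list tests called, 15 were called with an estimated correlation, and fry called 64 in its mixed form.

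Leaving out each array in turn gave 5243 to 6053 genes for PMA against vehicle, 11 to 16 for DOC, 31 to 53 for DOC plus PMA against PMA, 5 to 14 for the interaction, and correlations of 0.0862 to 0.301 for the DOC effects, 0.948 to 0.964 for the PMA effects and −0.106 to −0.0275 for the main effects. With the replicate number as a block, 6108 genes passed for PMA against vehicle, 16 for DOC, 56 for DOC plus PMA against PMA and 15 for the interaction. The numbers were taken to pair only PMA with DOC plus PMA, as 15 of all 24 same-number pairs had deviations correlated above 0.1 (−0.164 to 0.549). The median was 0.163 for these pairs against −0.0554 for others, and 10 of 16 arrays correlated best with their own number, a hint from the data that some same-number arrays share a source of variation. Under this block ITPKA, KLF7, RGCC and SYBU, named after their values were seen, were lost for DOC plus PMA against PMA (adjusted p = 0.0515 to 0.0846). The block gained 4 gene results, of which PTGS2 lay in that comparison. The others, each lower for PMA against vehicle, were POSTN (adjusted p = 0.0389), NR3C2 (0.0395) and BATF2 (0.0490). It also gained 4 list tests, interferon-induced genes for PMA (adjusted p = 0.0432) and DOC (0.000123), and ERK feedback (0.0417) and phorbol ester receptors (0.0433) for DOC plus PMA against PMA. It changed no other call of a named gene or list. Of 293 results for named genes, 202 passed. None reversed, and 1 to 25 were lost and 0 to 6 gained in each of 24 settings, the left-out arrays included. The 60th percentile filter kept 244 of them, with 175 passing and 0 lost. They were not recomputed for every probe set, the 1.5-fold minimum or the 2 groups alone. No read depth limits arrays, but signals near the array floor understate changes.

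For 7 of the 8 counts, under 0.05 of the splits of the arrays into groups of the same sizes gave as many genes. Splits that mix a pair of groups also put any treatment effect into the within-group spread, which lowers their counts. Chance as the source is thus made less likely, not excluded. The 35 splits of a pair of groups gave at most 0 genes against the real 5869 for PMA, 1 against 15 for DOC, 0 against 5476 for DOC plus PMA, and 0 against 5323 for DOC plus PMA against DOC. In 100 splits or reorderings, the highest other count was 4 against 11 for the interaction, 20 against 54 for the DOC main effect and 4911 against 7146 for the PMA main effect. In each of the 7, only 1 split, the real one, gave as many. For DOC plus PMA against PMA only 8 splits part every same-number pair, too few for a share under 0.05, and the highest other was 0 against 48, and 1 against 56 with the block.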

Other observations

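The gene lists and families described here were chosen after the data were seen, while what the aryl hydrocarbon receptor and retinoic acid tests would show was set down before they were run. With PMA, chaperones of the heat shock response rose, 7 of 13 tested, with 0 falls. HSPA1B, an inducible HSP70, rose by 0.79, the HSP110 chaperone HSPH1 by 0.77, the co-chaperones BAG3 and DNAJB1 by 0.72 and 0.68, and HSPA8 by 0.43. This list was 1 of 3 added, and its shift had camera p = 0.000588, and p = 0.0492 with an estimated correlation. The latter was 0.0660 after cyclic loess, with 7 rises, and 0.0701 with a common median, with 8.

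Of 5 gene families set apart by symbol and tested for PMA against vehicle, dual-specificity phosphatases, which switch off MAP kinases, had 10 rises and 5 falls among 19 (camera p = 0.00369, and p = 0.0928 with an estimated correlation), and the same numbers under both other scalings, where the latter p was 0.111 after cyclic loess and 0.0418 with a common median. Zinc finger genes had 162 falls and 72 rises among 439. Falls made up 36.9% of them against 29.3% of all genes, with p = 0.582 at an estimated correlation. After cyclic loess they had 142 falls and 90 rises, and with a common median 133 and 111. Histone genes had 12 falls and 0 rises among 33 (p = 0.380 with an estimated correlation), 10 and 0 after cyclic loess, and 8 and 1 with a common median. Ribosomal protein genes had 3 falls and 1 rise among 69 (p = 0.844 with an estimated correlation), but 8 falls and 1 rise after cyclic loess (p = 0.0285) and 2 falls and 4 rises with a common median (p = 0.876). Solute carrier genes were not called under any of these scalings (p = 0.948, 0.896 and 0.939 with an estimated correlation).

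TIPARP and CYP1B1, both known targets of the aryl hydrocarbon receptor, rose with DOC in the presence of PMA, by 2.00 and 0.83. CYP1B1 was named after its value was seen (adjusted p = 0.0417) and did not pass without vehicle replicate 2, 3 or 4, PMA replicate 2, 3 or 4, DOC replicate 3, or DOC plus PMA replicate 1, 2 or 4 (0.0515 to 0.170). The other 7 tested targets of that receptor had a median of −0.063. CYP26A1 is a known target of retinoic acid, and the other 7 tested members of a retinoic acid list had a median of 0.037 in the same comparison, although the list with CYP26A1 had camera p = 0.00901 at an estimated correlation. These medians leave out the genes that passed, and some members lay near the array floor, so a general rise of either group stays open beside an effect specific to these genes.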
